A study of Arabidopsis thaliana with 8 samples.

How the data were processed

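Transcript levels were measured by RNA sequencing in roots and shoots of 6-week-old Arabidopsis thaliana grown in hydroponic solution. Per the labels, wild-type (WT, Columbia) and spl7-2 plants, whose mutation is described as a knock-down of the transcription factor SPL7, received 0.25 µM copper sulfate or no added copper for the last 3 weeks. Each 400 mL vessel held 2 plants, which spent the last 48 h in long days. Total RNA from 100 mg of tissue was isolated, 10 µg of it entered each library, and polyadenylated RNA was primed with oligo-dT, per the labels' protocols. The 8 samples are the 8 combinations of tissue, genotype and copper supply, and the labels state 2 independent experiments for each. This gave 16 libraries, sequenced in 19 runs. Runs of one experiment were summed and counted once, so n = 2 in every group. The experiment number was taken from the deposited names.

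The deposited values are counts of uniquely aligned reads at each alignment position and alignment length. Per the deposited description, the authors aligned reads of 35 bases to the TAIR7 assembly with SOAP (version not given in the sources used here), allowing up to 2 mismatches. Reads with more than 1 match were eliminated, and reads that did not align were shortened base by base, to 21 bases at the shortest, until a perfect unique match was found, per the same description. The alignment lengths in the data run from 21 to 35 bases. A total of 1710780 entries hold 0 unique reads and were not used. Strand is not recorded, so reads of a gene and of an antisense partner cannot be told apart. Reads that match several members of a gene family equally well had been eliminated upstream, so counts of near-identical genes such as FRO4 and FRO5 cover only their distinct stretches.

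The available annotation belongs to a later assembly, TAIR10.1. The builds were compared in windows of 100 kb by placing the annotated pattern of exons and introns on the pooled 35-base alignments, searching 30 kb either side. A window was used where the best place lay within 35 bases of the annotation's own coordinate and another such window lay within 2 windows of it, or where it was a single unplaced window between used ones. Of the windows that coincided, 2 stood alone and were left out. This held for 530 of 1188 windows, 521 of them placed themselves, with shifts from -25 to 20 bases. They cover 53.0 Mb, 44.6% of the windows of the 5 chromosomes. The usable length was 13.2 Mb on chromosome 1, 2.7 Mb on chromosome 2, 9.1 Mb on chromosome 3, 17.1 Mb on chromosome 4 and 10.9 Mb on chromosome 5. These windows hold 13542 of 27444 annotated protein-coding genes (49.3%). Genes elsewhere, among them COPT1, COPT2, ZIP2, CSD2, CCH and FIT, were not analysed here. Because the builds are offset, genes are given by chromosome without coordinates.

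An alignment was counted for a gene when its centre lay in the gene's exons, with protein-coding genes given priority and bases shared by genes of one class given to none. Counts on genes ranged from 782707 to 2790429 per library. At that depth 3 counts correspond to 1.08 to 3.76 CPM (counts scaled to a library of 1e6), depending on the library. A fold against a group at 0 was computed against a floor of 3 counts over the group and is written as "at least". With 1 to 3 counts the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only.

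Roots and shoots were fitted apart with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with 1 coefficient per group, TMM scaling and the package's expression filter. The contrast of tissues used all 16 libraries and took them as independent. Whether the roots and shoots of an experiment came from the same plants was not tested. The Benjamini-Hochberg adjusted p threshold was 0.05. Errors of log2 folds, written SE, are the absolute log2 fold divided by the square root of its F statistic. They only approximate a standard error. For SPL7 between sufficient roots this gave 0.27, against a standard error of 0.34 by DESeq2. CPM values are means ± SD over n = 2. In total 9273 genes were tested in roots, 9035 in shoots and 10163 in the joint fit. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the estimated correlation beside it, where at least 5 members were tested. The 18 lists cover the copper deficiency response, targets of copper-responsive microRNAs, copper handling, iron uptake, iron storage, zinc transport, photosynthesis (leaf cells), chlorophyll synthesis, root hair and endodermis (root cells), flavonoid synthesis, jasmonate, salicylate and pathogen response, heat shock proteins, the circadian clock, phosphate starvation, sulfate starvation, other superoxide and peroxide enzymes, and SPL7. Counts of members below refer to tested members, since others lay outside the windows used or under the expression filter. Of 15 copper deficiency genes 5 were tested in each tissue, and of 12 microRNA targets 6. Of 40 photosynthesis genes 13 were tested in roots and 19 in shoots, and of 11 heat shock genes 1 and 2.

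The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes SPL7, the 10 highest and 10 lowest log2 folds among genes past the threshold whose experiments separate by group and whose mean is at least 1 CPM, and list members past the threshold (up to 4 examples a list by smallest p, or up to 2 as values where none passes). For an interaction, the differences of both experiment numbers had to have the sign of the fold. A count of 5 or fewer is named in full. The alternatives fixed then were other scalings, DESeq2 1.42.0, other filters, a replicate block, first runs only, whole gene bodies, distinct start positions, only the groups compared, all libraries in one fit, and leaving out each library of the groups compared. A call that held whichever library was left out refers to these libraries only. Full-length alignments only, larger runs only and thinning to the smallest library were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for counting and figures. A library that stands alone after its partner is left out is assumed to vary like the other groups.

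The fits were tested on simulated counts with 200 changed genes. For the WT root response (9069 genes), 33% of genes changed 2-fold and 82.8% of those changed 4-fold were called, and 3.4% of calls were unchanged genes. For the WT shoot response (8889 genes) the values were 32.3%, 77.6% and 4.4%. The counts were drawn with the spread of each gene as fitted by edgeR, the same for all groups. Groups of unequal spread or a deviating library were therefore not simulated, and the shares hold only under that model. Camera called 0 unchanged lists in either simulation, but genes were drawn independently there. How often camera calls an unchanged list of correlated genes was therefore not tested. In the shoot data the estimated correlation of the photosynthesis list was 0.745. The experiments of a group differed beyond sampling noise (mean chi-square per gene 4.4 to 10.14). Runs of one experiment differed less, at 1.26 to 1.93, but still by more than sampling noise alone. The biological coefficient of variation was 0.178 in roots and 0.195 in shoots.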

Results

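The data are RNA sequencing counts from 16 Arabidopsis libraries, 2 independent experiments for each combination of tissue (roots, shoots), genotype (WT, spl7) and copper supply (0.25 µM, called sufficient, or none added for 3 weeks, called deficient). SPL7 is a transcription factor that activates copper deficiency genes, and the design asks how its loss alters the transcript response to low copper in each tissue. Counts on genes per library lay between 782707 (spl7 root sufficient replicate 2) and 2790429 (WT root sufficient replicate 1). In a principal component analysis, the first component (38.7% of root variance) placed the spl7 deficient roots at 26.7 and 31.5 and no other root library above 2.4. In shoots WT deficient replicate 2 stood apart from its group on the second component, at 28.8 against 3.1 for replicate 1.

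SPL7 (AT5G18830, chromosome 5) had a lower mean level in spl7 than in WT in each tissue and copper supply. In roots its level was 97.3 ± 9.02 CPM (SD, n = 2) in WT and 25.8 ± 7.83 in spl7 with sufficient copper, and 108.2 ± 9.05 against 18.24 ± 2.26 under deficiency. In shoots it was 53.4 ± 5.82 against 16.2 ± 0.0607 and 59.2 ± 6.1 against 17.42 ± 4.41. By the edgeR quasi-likelihood test the SPL7 log2 folds were -2.0 ± 0.27 (adjusted p = 0.00099) and -2.56 ± 0.26 (adjusted p = 2.99e-06) in sufficient and deficient roots and -1.76 ± 0.29 (adjusted p = 0.0153) in deficient shoots, while the log2 fold of -1.71 ± 0.29 in sufficient shoots had an adjusted p of 0.0797. The SPL7 call in sufficient roots ended without spl7 root sufficient replicate 1 (log2 -1.63, adjusted p = 0.353), and that in deficient shoots without WT shoot deficient replicate 2 (-1.66, adjusted p = 0.0942) or spl7 shoot deficient replicate 2 (-1.52, adjusted p = 0.299). In sufficient shoots the SPL7 transcript passed with DESeq2 (adjusted p = 0.0105), in edgeR without the expression filter (0.000179) and with all 16 libraries in one fit (0.0153). SPL7 also passed there when adjusted over its list of 1 gene alone, which applies no correction for the other genes. SPL7 did not pass the test of the copper response in any group, with log2 folds from -0.41 ± 0.31 (spl7 root) to 0.15 ± 0.27 (WT shoot).

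The copper response of WT roots included FSD1, FRO4, FRO5, YSL2, CSD1 and CCS. FSD1 (AT4G25100, chromosome 4), the iron superoxide dismutase of chloroplasts, rose from 38.5 ± 21.7 to 2591 ± 114 CPM (log2 6.03 ± 0.31, adjusted p = 1.92e-10). FRO4 and FRO5 (AT5G23980 and AT5G23990, chromosome 5), neighbouring metal reductases of the root surface, rose by log2 5.36 ± 0.42 (FRO4, adjusted p = 8.58e-08) and at least 3070-fold (FRO5, 7952 counts against 0). The size for FRO4 is uncertain, with log2 8.49 without WT root sufficient replicate 1, which leaves 1 count in the sufficient group. YSL2 (AT5G24380, chromosome 5), a transporter of metal-nicotianamine complexes, rose by log2 2.75 ± 0.32. CSD1 (AT1G08830, chromosome 1), the cytosolic copper/zinc superoxide dismutase, fell from 1046 ± 152 to 70.1 ± 35.0 CPM (log2 -3.93 ± 0.26, adjusted p = 6.39e-09), and its copper chaperone CCS fell from 239.5 ± 19.4 to 56.1 ± 11.7 CPM (log2 -2.10 ± 0.20).

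**Figure D1:**
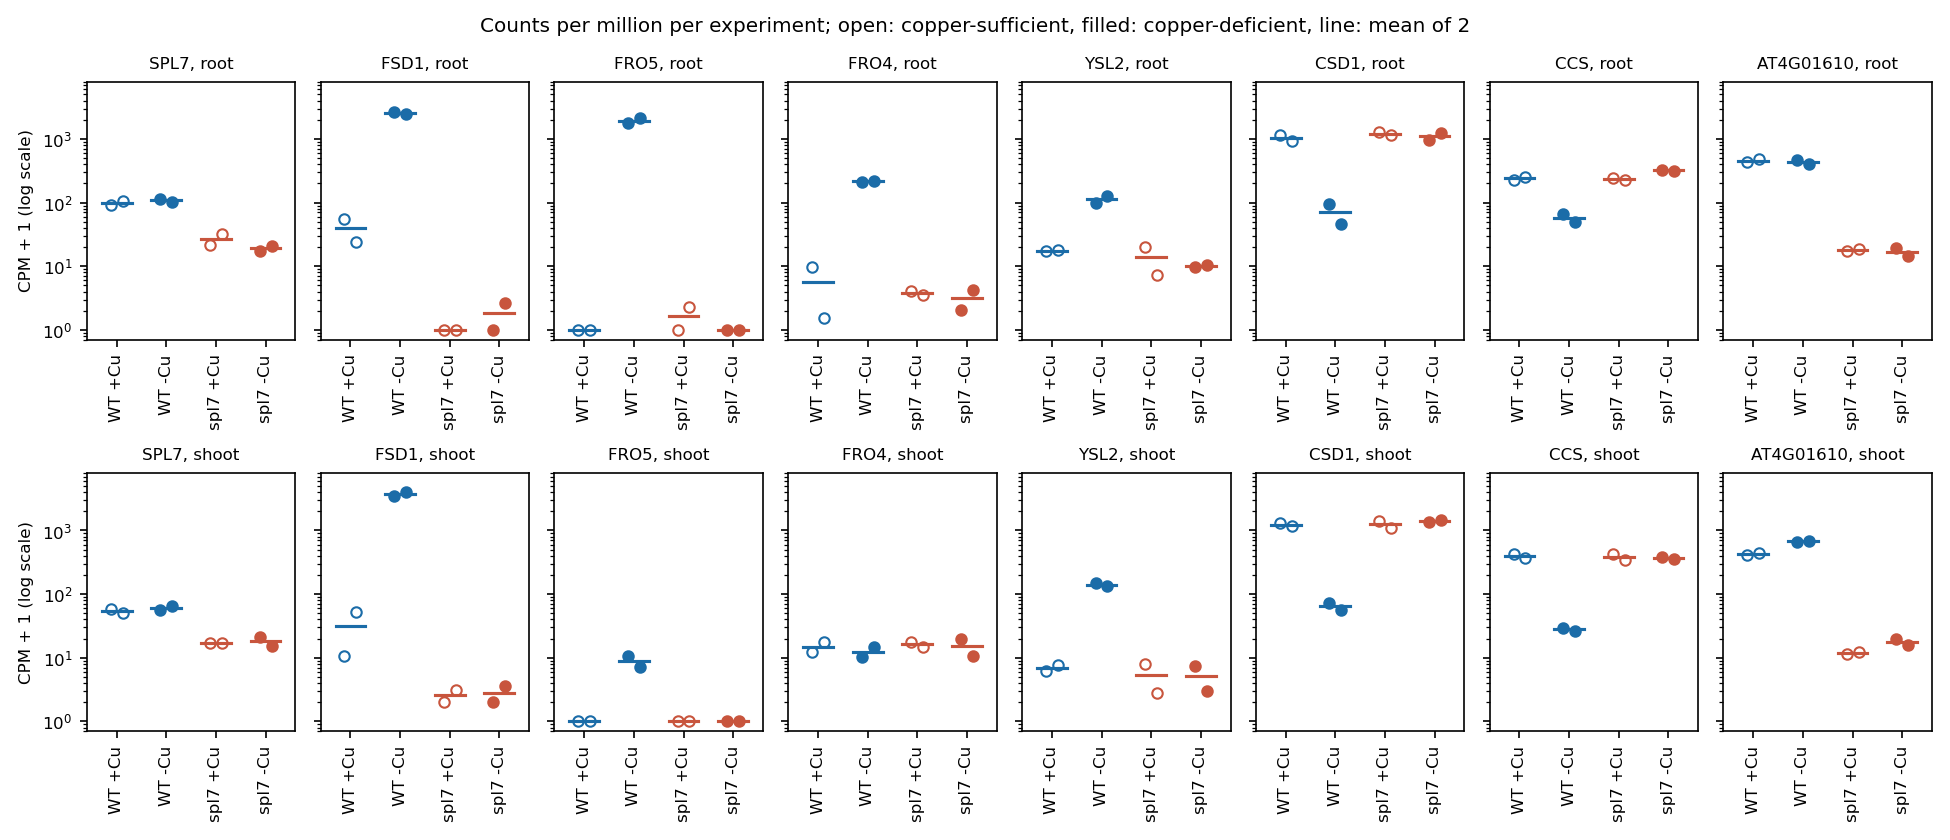
Levels of SPL7, FSD1, FRO5, FRO4, YSL2, CSD1, CCS and AT4G01610 in CPM + 1 on a log scale, with roots in the upper panels and shoots in the lower. Points are the 2 experiments of a group (open, copper-sufficient; filled, copper-deficient) and lines their mean; in WT roots FSD1 lies at 38.5 CPM with sufficient and 2591 CPM with deficient copper, whereas in spl7 roots it lies at 0 and 0.826 CPM.

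The list of the copper deficiency response has 15 members, of which 8 lay in the windows used and 5 were tested. Of these 5 genes, 4 rose in WT roots (5 adjusted over the list alone), the reductase FRO3 having log2 0.93 ± 0.20 and an adjusted p of 0.0615. Of 6 tested copper microRNA targets, 4 fell (5 adjusted over the list alone): CSD1, CCS, the plantacyanin ARPN (log2 -1.86 ± 0.31) and the cytochrome oxidase subunit COX5B-1 (log2 -1.60 ± 0.23). The camera calls of both lists held with an estimated correlation (adjusted p = 0.00253 and 0.00278). None of the 11 tested copper handling genes passed in edgeR (1 adjusted over the list alone), the metallothionein MT1C having log2 1.04 ± 0.23 and an adjusted p of 0.0703. Outside the lists, AT4G28790, a basic helix-loop-helix gene, rose from 2.92 ± 1.08 to 62.8 ± 3.85 CPM, and the peroxidase PRX52 rose to 76.5 times its level in sufficient roots (counting interval 13.3 to 3070, 66 counts against 1). Counts on AT5G14550 (log2 2.63 ± 0.21) and the nitrate transporter gene NRT2.7 (log2 4.84 ± 0.35) rose as well, but strand is not recorded and these genes overlap or adjoin MIR398B and MIR398C, so the transcript that rose is uncertain. The cytokinin response regulator ARR7 (log2 -1.44 ± 0.25) and the methyltransferase IGMT2 (-1.49 ± 0.27) fell.

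**Figure D2:**
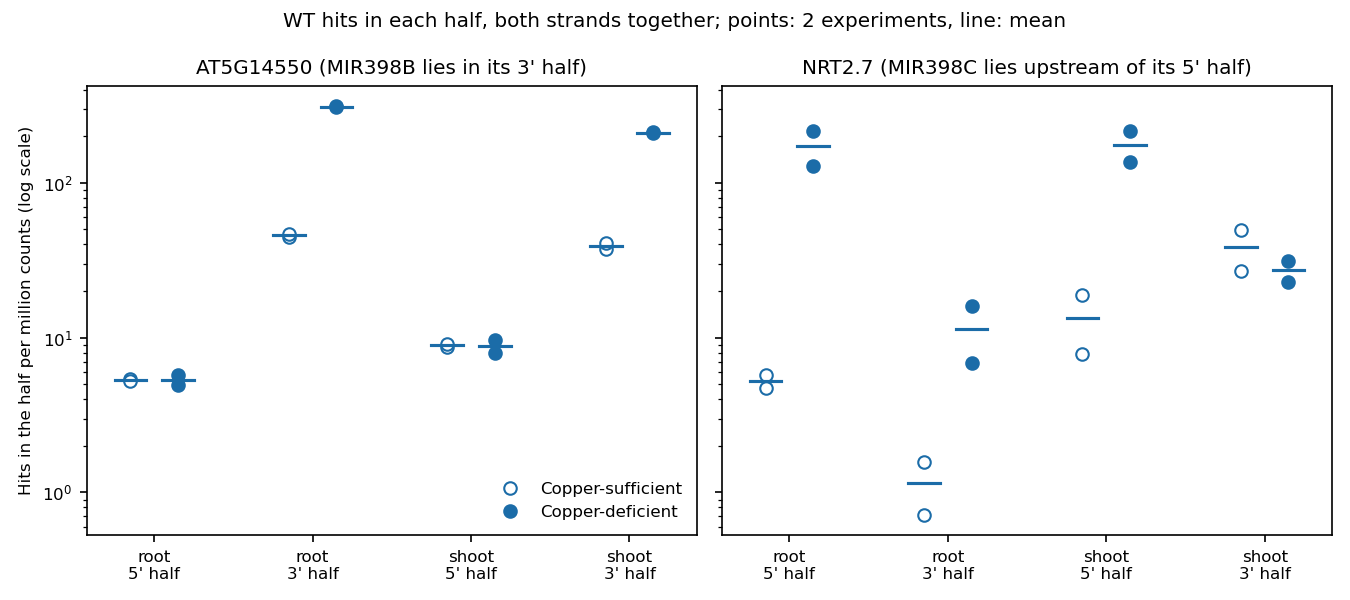
Hits (CPM scale) in the 5' and 3' parts of AT5G14550 and NRT2.7 in WT roots and shoots, on a log scale, with a point per experiment. In roots the 3' part of AT5G14550, which overlaps MIR398B, holds 213 hits with sufficient and 1258 hits with deficient copper, and its 5' part 25 and 22.

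In total 25 genes passed in WT roots, 19 higher and 6 lower. The count was 13 without WT root deficient replicate 2 (8 higher, 5 lower) and 62 without WT root deficient replicate 1, and without sufficient replicate 2 the split was 13 higher and 11 lower. The calls of FRO5, FSD1, FRO4, NRT2.7, AT4G28790, YSL2, AT5G14550, CSD1, CCS and COX5B-1 held whichever library was left out. ARPN lost its call without WT root sufficient replicate 1 (adjusted p = 0.0606), PRX52 without that library or WT root deficient replicate 2 (up to 0.362), IGMT2 without WT root sufficient replicate 2 or deficient replicate 1 (up to 0.126), and ARR7 without WT root sufficient replicate 2 or deficient replicate 2 (up to 0.129).

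**Figure D3:**
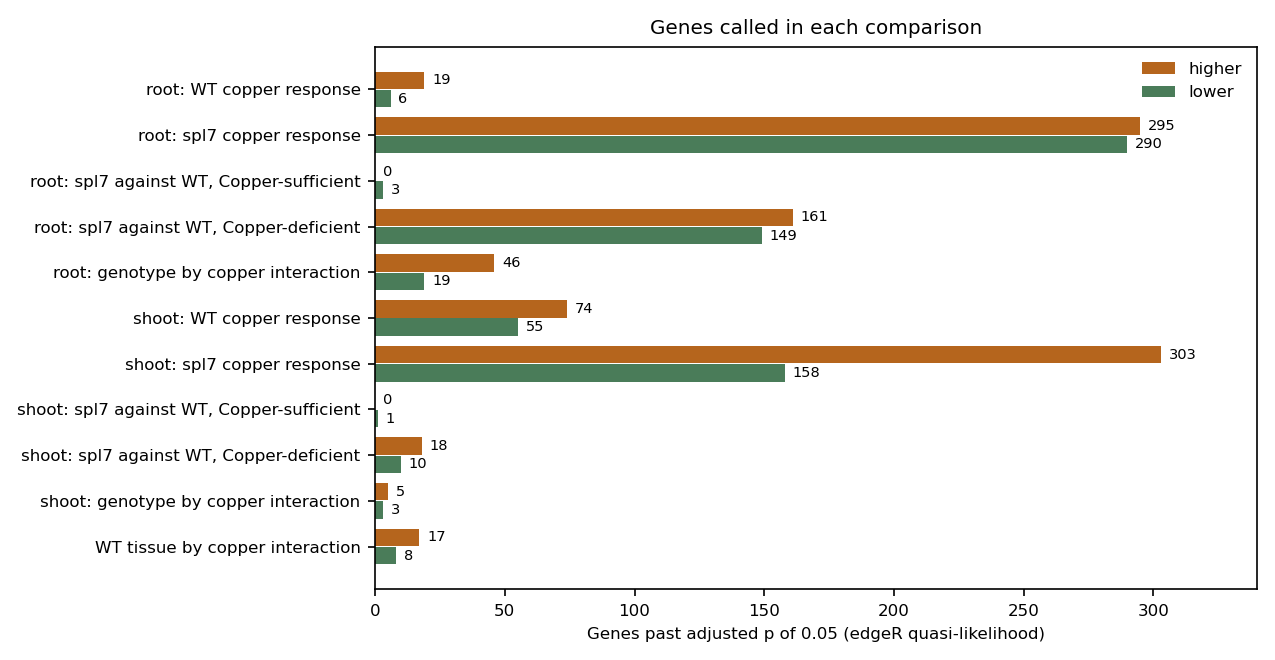
Number of genes past the edgeR threshold in each comparison, with bars for higher and lower genes. The copper response of WT roots holds 25 such genes and that of spl7 roots 585.

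In spl7 roots none of the 5 tested copper deficiency genes and 6 tested microRNA targets passed in edgeR. FSD1 stayed at 0.826 ± 1.17 CPM under deficiency and at 0 with sufficient copper, FRO5 at 0 and 0.626 ± 0.885 CPM, CSD1 at 1117 ± 193 and 1216 ± 85.4 CPM. The peroxidase PRX52 rose at least 82.8-fold (302 counts against 0), the nitrilase NIT4 by log2 5.76 ± 0.69 (adjusted p = 1.86e-05; 6 counts against 0 in the sufficient experiments), the transcription factor WRKY45 by log2 5.25 ± 0.45 (adjusted p = 2.86e-07), and the sucrose synthase SUS3 to 49.1 times its sufficient level (counting interval 16.5 to 240). Among lower genes, the cytochrome P450 gene CYP712A2 fell at least 15.4-fold, the arabinogalactan protein gene AGP41 by 3.54 on the log2 scale and the malate transporter gene ALMT1 to a level lower by a ratio of 15.2 (counting interval 3.79 to 132).

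Among the 14 tested iron uptake genes 3 rose in spl7 roots (4 adjusted over the list alone): the vacuolar transporter ZIF1 (log2 1.09 ± 0.19), the ferric reductase FRO2 (0.89 ± 0.22) and the iron transporter IRT1 (0.72 ± 0.21). Of 4 iron storage genes the vacuolar transporter VTL1 rose (log2 1.54 ± 0.33; 1 adjusted over the list alone). Of 11 copper handling genes the metallothionein MT2A rose (log2 1.31 ± 0.24; 3 adjusted over the list alone), and of 8 zinc genes the zinc exporter HMA2 fell (log2 -1.35 ± 0.39; 1 adjusted over the list alone). In the list of root hair and endodermis genes (7 tested, 3 adjusted over the list alone), CASP4 and CASP2, which build the Casparian strip, fell by 1.67 and 1.26 on the log2 scale, and the nitrate transporter NRT2.1 rose (0.73 ± 0.20). Of 7 jasmonate genes VSP1 (log2 3.25 ± 0.69) and JAZ1 (0.72 ± 0.18) rose (3 adjusted over the list alone). Single members passed for salicylate (FMO1, a monooxygenase of systemic resistance, log2 -1.90 ± 0.41, 1 of 4, and 1 adjusted over the list alone) and the clock (PRR7, log2 0.72 ± 0.18, 1 of 6, and 3 adjusted over the list alone). In the phosphate list (8 tested, 2 adjusted over the list alone) PAP17 rose (log2 1.1 ± 0.3) and AT4 fell (-1.43 ± 0.36), and among 6 peroxide enzymes (2 adjusted over the list alone) the catalase CAT1 rose (1.24 ± 0.22) and the ascorbate peroxidase APX1 fell (-0.60 ± 0.15). Of 13 photosynthesis genes, which mark leaf cells, PSBQ2 fell by a ratio of 26.8 (counting interval 4.33 to 1100; 4 adjusted over the list alone).

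A total of 585 genes passed in spl7 roots, 295 higher and 290 lower. The split was 267 and 358 with scaling by total counts and 274 and 326 by distinct start positions. Camera called none of the lists (smallest adjusted p 0.0724, for iron uptake and for jasmonate). The count was 213 without spl7 root sufficient replicate 1, 344 without deficient replicate 1 and 243 without deficient replicate 2. The calls of PRX52, NIT4, SUS3, WRKY45, MT2A, ZIF1 and CAT1 held whichever library was left out. The sizes of NIT4 and SUS3 are uncertain, with log2 10.67 and 9.52 without spl7 root sufficient replicate 1, which leaves a sufficient group at 0. Without spl7 root sufficient replicate 1 the calls of FRO2, IRT1, VTL1, HMA2, CASP2, NRT2.1, VSP1, JAZ1, FMO1, PRR7, AT4, PAP17, APX1, PSBQ2, ALMT1 and CYP712A2 ended, all but PRR7 and AT4 also without spl7 root deficient replicate 2, with highest adjusted p from 0.0682 (CYP712A2) to 0.43 (IRT1). Of these, IRT1, JAZ1, PRR7, AT4, PAP17, APX1, PSBQ2, ALMT1 and CYP712A2 also ended without spl7 root deficient replicate 1, and HMA2, JAZ1, PRR7, PAP17, PSBQ2 and ALMT1 without spl7 root sufficient replicate 2. CASP4 and AGP41 lost theirs without spl7 root deficient replicate 2 (adjusted p = 0.0721 and 0.132).

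With sufficient copper, 3 genes differed between spl7 and WT roots by edgeR, all lower in spl7. FSD1 was at least 41.8-fold lower (194 counts in WT, 0 in spl7) and SPL7 lower as given above. AT4G01610 (chromosome 4), a cathepsin B-like protease gene, stood at 16.9 ± 0.954 CPM in spl7 and 455 ± 38.2 CPM in WT (log2 -4.77 ± 0.23, adjusted p = 7.22e-11). None of the 6 tested microRNA targets passed (0 adjusted over the list alone), and 413 genes had an unadjusted p under 0.05. Camera called the 14 iron uptake genes higher in spl7 (adjusted p = 0.0247; adjusted p = 0.451 with an estimated correlation), with 0 of them past the edgeR threshold. Without spl7 root sufficient replicate 1 only AT4G01610 passed, FSD1 having an adjusted p of 0.078, and without WT root sufficient replicate 2 the count was 10.

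Under copper deficiency, spl7 roots held lower levels of the copper deficiency genes than WT roots and higher levels of the microRNA targets. FSD1 was lower by a ratio of 3160 (counting interval 1080 to 15300, 3 counts against 10405), FRO5 at least 2410-fold, FRO4 by log2 -6.58 ± 0.50 (adjusted p = 4.01e-08) and YSL2 by log2 -3.64 ± 0.36. CSD1 was higher by log2 4.02 ± 0.26 (adjusted p = 3.33e-09), CCS by 2.53 ± 0.20, ARPN by 1.99 ± 0.32 and COX5B-1 by 1.37 ± 0.23. Thus 4 of 5 copper deficiency genes were lower (4 adjusted over the list alone) and 4 of 6 microRNA targets higher (5 adjusted over the list alone), and both camera calls held with an estimated correlation (adjusted p = 0.00862 and 0.00921). Outside the lists, the aminotransferase gene PYD4 (log2 3.44 ± 0.36), WRKY45 (3.05 ± 0.34) and the threonine aldolase gene THA1 (3.0 ± 0.31) were higher, and AT4G01610 was lower (log2 -4.77 ± 0.23). NRT2.7, with the limit of strand given above, was lower by log2 -5.68 ± 0.40.

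Of 14 iron uptake genes 4 were higher in deficient spl7 than in deficient WT roots (5 adjusted over the list alone): ZIF1 (log2 1.0 ± 0.18), FRO2 (1.05 ± 0.22), and CYP82C4 and S8H (1.62 ± 0.36 and 1.34 ± 0.34), hydroxylases of coumarin synthesis. Camera called this list higher (adjusted p = 8.29e-05; adjusted p = 0.119 with an estimated correlation). The interaction test passed for 0 of the 14 genes (3 adjusted over the list alone), ZIF1 having log2 0.94 ± 0.26 (adjusted p = 0.123) and CYP82C4 1.63 ± 0.50 (adjusted p = 0.183). Of 11 copper handling genes MT2A (log2 1.15 ± 0.23) and MT3 (0.74 ± 0.20) were higher and MT1C lower (-0.94 ± 0.23), with 5 adjusted over the list alone. Of 8 zinc genes the nicotianamine synthase gene NAS1 was higher (log2 1.29 ± 0.33) and HMA2 lower (-1.84 ± 0.37), with 2 adjusted over the list alone. Of 7 root hair and endodermis genes (5 adjusted over the list alone) CASP2 and CASP4 were lower (log2 -1.16 ± 0.27 and -1.35 ± 0.32) and NRT2.1 higher (0.81 ± 0.20). Of 8 phosphate genes PAP17 (1.07 ± 0.29; 2 adjusted over the list alone) and of 6 peroxide enzymes CAT1 (0.98 ± 0.21; 1 adjusted over the list alone) were higher.

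In total 310 genes passed in deficient roots, 161 higher and 149 lower in spl7. The split turned to 144 and 163 with scaling by total counts, 159 and 197 by distinct start positions and 212 and 262 without the expression filter. The count was 87 without WT root deficient replicate 1, 189 without spl7 root deficient replicate 1 and 107 without spl7 root deficient replicate 2. The calls of CSD1, PYD4, WRKY45, THA1, FRO5, FSD1, FRO4, NRT2.7, AT4G01610, YSL2, CCS, ARPN, COX5B-1, ZIF1 and SPL7 held whichever library was left out. PYD4 and WRKY45 had log2 4.99 and 4.12 without WT root deficient replicate 2, and NRT2.7 -6.76 without spl7 root deficient replicate 1. Without spl7 root deficient replicate 2 the calls of FRO2, CYP82C4, S8H, MT2A, MT3, HMA2, NAS1, CASP2, CASP4, NRT2.1, PAP17 and CAT1 ended, and that of MT1C without spl7 root deficient replicate 1. All of these but CYP82C4, S8H and HMA2 also ended without WT root deficient replicate 1, with highest adjusted p from 0.0934 (FRO2) to 0.448 (NAS1). Those of FRO2, CYP82C4, S8H, MT1C, MT3, NAS1 and PAP17 also ended without WT root deficient replicate 2, and those of S8H, MT3, CASP2, PAP17 and CAT1 without spl7 root deficient replicate 1.

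The response to copper differed between genotypes in roots for 65 genes by the interaction test, 46 with a higher and 19 with a lower fold in spl7. This split depended on the counting: by distinct start positions 30 folds were higher and 34 lower, with 39 genes called by both counts, and without the expression filter 102 were higher and 97 lower. DESeq2 gave 47 and 32, and edgeR without WT root sufficient replicate 1 gave 48 and 40. CSD1 (log2 difference 3.81 ± 0.34, adjusted p = 3.47e-06) and CCS (2.55 ± 0.27, adjusted p = 2.17e-05) fell in WT roots, whereas their levels in spl7 roots did not pass a test. FRO4 (-5.79 ± 1.12) and YSL2 (-3.46 ± 0.53) rose in WT roots and did not pass in spl7 roots, and FRO5, with groups at 0, passed with an adjusted p of 0.0258. The osmotin gene OSM34 (3.0 ± 0.45), the transcription factor gene Rap2.6L (2.74 ± 0.40) and the lipid transfer protein gene AZI1 (4.31 ± 0.77) had higher folds in spl7, and the sodium transporter gene HKT1 (-2.23 ± 0.37) and the aquaporin gene DELTA-TIP (-1.93 ± 0.38) lower folds. By list, 3 of 5 copper deficiency genes (3 adjusted over the list alone) and 4 of 6 microRNA targets (5 adjusted over the list alone) passed, and both camera calls held with an estimated correlation (adjusted p = 0.0112 and 0.0115). The copper deficiency genes that passed were FRO4, YSL2 and FRO5, whereas FSD1 and FRO3 did not pass. The jasmonate list was called by camera (adjusted p = 0.0444; adjusted p = 0.429 with an estimated correlation) with 1 of 7 members past the threshold, VSP1 (4.0 ± 0.87; 1 adjusted over the list alone). The count was 29 without spl7 root sufficient replicate 1, 33 without WT root deficient replicate 1, 41 without spl7 root deficient replicate 1 and 36 without spl7 root deficient replicate 2. CSD1, OSM34 (4.01 without WT root deficient replicate 2), Rap2.6L, AT5G14550, HKT1 and CCS passed whichever library was left out. FRO4 had -8.92 without WT root sufficient replicate 1. Without spl7 root sufficient replicate 1 the calls of FRO4, YSL2, AZI1, VSP1 and DELTA-TIP ended (highest adjusted p 0.486, 0.413, 0.0883, 0.29 and 0.127), those of AZI1, VSP1 and DELTA-TIP also without spl7 root deficient replicate 2, and FRO5 lost its call without spl7 root sufficient replicate 2. Of the microRNA targets, ARPN (2.36) lost its call without spl7 root deficient replicate 2 (adjusted p = 0.0592), and COX5B-1 (1.65) without WT root deficient replicate 2, spl7 root sufficient replicate 2 or spl7 root deficient replicate 2 (up to 0.067).

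In WT shoots copper deficiency raised FSD1 from 30.96 ± 30.2 to 3770 ± 428 CPM (log2 6.85 ± 0.48, adjusted p = 5.73e-06) and YSL2 from 5.96 ± 1.04 to 140.5 ± 11.8 CPM (log2 4.52 ± 0.47). It lowered CSD1 from 1237 ± 75.7 to 64.1 ± 12.1 CPM (log2 -4.27 ± 0.23, adjusted p = 4.61e-07), CCS from 395.5 ± 33.5 to 26.9 ± 1.56 CPM (log2 -3.88 ± 0.22), and ARPN from 51.9 ± 5.45 to 2.637 ± 1.3 CPM (log2 -4.24 ± 0.41). FMO1 (log2 3.91 ± 0.51), the transporter gene ABCG40 (3.80 ± 0.36) and the glucanase gene AT4G16260 (3.35 ± 0.34) rose. Lower genes included AT3G19680 (log2 -3.98 ± 0.51), EXO (-3.89 ± 0.65) and PHI-1 (-4.25 ± 0.87), the last 2 related genes of cell growth, the homeobox gene HAT1 (-2.87 ± 0.45) and the expansin-like EXLA2 (-2.64 ± 0.52).

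Of 5 copper deficiency genes 2 rose in WT shoots (3 adjusted over the list alone), FSD1 and YSL2. The median log2 fold of this list was 4.52, or 2.91 with FRO5 at its bound, and its camera call was lost (adjusted p = 0.0561 with an estimated correlation). FRO5 itself stood at 7.98 ± 2.38 CPM under deficiency and 0 with sufficient copper. Of 6 microRNA targets 4 fell (4 adjusted over the list alone), COX5B-1 (log2 -1.59 ± 0.27) among them, and the camera call held with an estimated correlation (adjusted p = 0.0253). Of 9 jasmonate genes 2 fell (4 adjusted over the list alone), the storage protein genes VSP1 (log2 -1.37 ± 0.19) and VSP2 (-1.59 ± 0.30), with adjusted p = 0.409 with an estimated correlation. Of 6 salicylate genes FMO1 rose (1 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation), and of 9 iron uptake genes F6'H1, a dioxygenase of coumarin synthesis, rose (log2 2.62 ± 0.44; 1 adjusted over the list alone). None of the 19 photosynthesis genes passed in edgeR (0 adjusted over the list alone), although camera called the list lower with a median log2 fold of -0.37 (adjusted p = 1.91e-05; adjusted p = 0.548 with an estimated correlation). The chlorophyll list had 0 of 6 past the threshold (1 adjusted over the list alone) and was called lower by camera (adjusted p = 0.0322; adjusted p = 0.409 with an estimated correlation).

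In total 129 genes passed in WT shoots, 74 higher and 55 lower. The count was 17 without WT shoot sufficient replicate 2, 73 without sufficient replicate 1 (36 higher, 37 lower) and 81 without deficient replicate 1 (38 higher, 43 lower). Without deficient replicate 2, which stood apart on the second principal component, 91 genes were higher and 32 lower, 77 of them shared with the 129. The calls of FSD1 (log2 8.61 without WT shoot sufficient replicate 2), YSL2, FMO1, ABCG40, AT4G16260, CSD1, ARPN, AT3G19680 and CCS held whichever library was left out. Without WT shoot sufficient replicate 2 the calls of EXO, PHI-1, HAT1, EXLA2, COX5B-1, VSP1, VSP2 and F6'H1 ended, with highest adjusted p from 0.0704 (COX5B-1, VSP1) to 0.449 (EXLA2). Leaving out WT shoot deficient replicate 2 also ended those of EXO, PHI-1 and EXLA2, leaving out deficient replicate 1 those of PHI-1, EXLA2 and VSP2, and leaving out sufficient replicate 1 those of PHI-1, COX5B-1 and F6'H1.

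In spl7 shoots, of 19 photosynthesis genes 14 fell under copper deficiency (19 adjusted over the list alone), among them PSBQ1 of photosystem II (log2 -1.06 ± 0.21), the antenna protein gene LHCB5, from 15080 ± 414 to 7541 ± 1600 CPM (-1.0 ± 0.2), PSAF of photosystem I (-1.03 ± 0.22) and LHCB4.2 (-1.18 ± 0.26). Camera called the list lower (adjusted p = 4.54e-16; adjusted p = 0.272 with an estimated correlation). FMO1 rose from 9.92 ± 3.82 to 300.0 ± 150 CPM (log2 4.95 ± 0.46, adjusted p = 6.7e-05), and AT1G26390, of the berberine bridge enzyme family, rose by log2 4.68 ± 0.42. AT4G16260 rose by log2 4.35 ± 0.35. Both tested heat shock genes, of 11 in that list, passed (2 adjusted over the list alone, too few for camera). HSP70-4 rose by log2 3.05 ± 0.35 and the chloroplast protein HSP21 at least 11.1-fold (27 counts against 0). AT4G20820 fell (log2 -2.17 ± 0.31). None of the 5 copper deficiency genes (0 adjusted over the list alone) and none of the 6 microRNA targets (1 adjusted over the list alone) passed in edgeR.

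**Figure D4:**
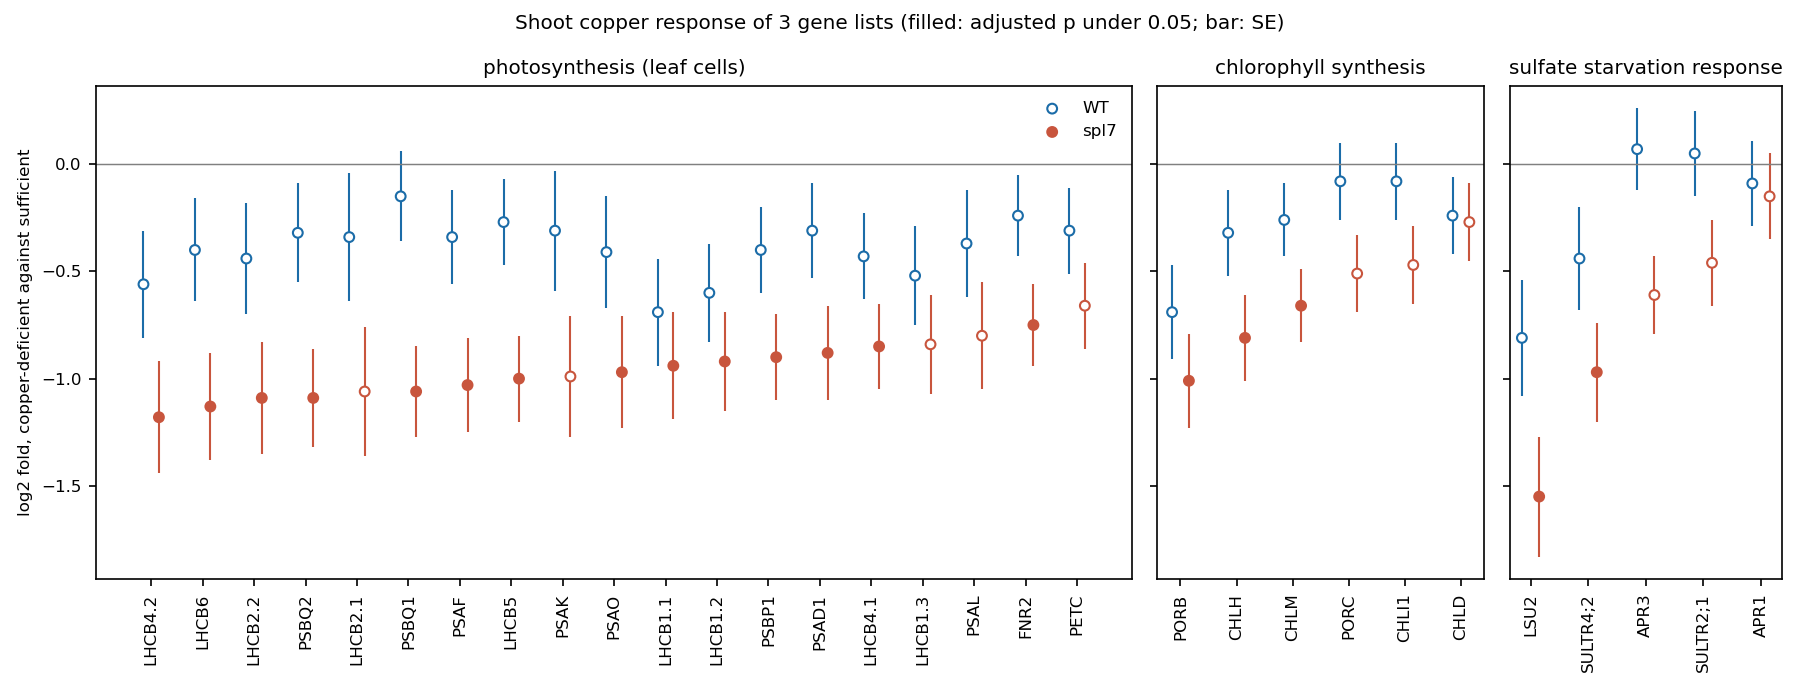
Log2 fold change (deficient against sufficient) ± SE of photosynthesis, chlorophyll synthesis and sulfate starvation genes in WT and spl7 shoots; filled points passed the edgeR threshold. In spl7 shoots 14 of 19 photosynthesis genes passed and in WT shoots 0 of 19, and the interaction test passed for 0 of 19.

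Of 6 chlorophyll synthesis genes 3 fell in spl7 shoots (5 adjusted over the list alone): PORB (log2 -1.01 ± 0.22), CHLH (-0.81 ± 0.20) and CHLM (-0.66 ± 0.17), with adjusted p = 0.154 with an estimated correlation. Of 5 sulfate starvation genes LSU2 (log2 -1.55 ± 0.28) and the vacuolar transporter SULTR4;2 (-0.97 ± 0.23) fell (4 adjusted over the list alone), and the adjusted p was 0.154 with an estimated correlation. Of 6 salicylate genes FMO1 rose (4 adjusted over the list alone), again with adjusted p = 0.154 with an estimated correlation. Of 8 zinc genes HMA2 (log2 -1.54 ± 0.25) and NAS1 (-1.03 ± 0.23) fell and PCR2 rose (2.88 ± 0.52), with 3 adjusted over the list alone. Of 12 copper handling genes the plastocyanin gene PETE2 fell (log2 -0.88 ± 0.20) and MT2A rose (0.84 ± 0.22), with 2 adjusted over the list alone. Single members rose for iron uptake (F6'H1, log2 2.15 ± 0.39, 1 of 9, and 1 adjusted over the list alone), jasmonate (JAZ1, 1.70 ± 0.28, 1 of 9, and 1 adjusted over the list alone) and phosphate (PAP17, 1.08 ± 0.21, 1 of 8, and 2 adjusted over the list alone).

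A total of 461 genes passed in spl7 shoots, 303 higher and 158 lower (65.7% higher). With scaling by total counts the split was 371 higher and 111 lower (77% higher), and the median log2 fold of all genes was 0.104. The count was 82 without spl7 shoot deficient replicate 2 (77 higher, 5 lower), 136 without sufficient replicate 1 (112 higher, 24 lower) and 238 without sufficient replicate 2. The calls of FMO1, AT1G26390 (log2 6.6 without spl7 shoot sufficient replicate 2), AT4G16260, AT4G20820 and HSP70-4 held whichever library was left out. Without spl7 shoot sufficient replicate 1 the calls of all 14 photosynthesis genes, PORB, CHLH, CHLM, SULTR4;2, PETE2, MT2A, PCR2, NAS1, JAZ1 and HSP21 ended. Those of LSU2, HMA2, F6'H1 and PAP17 ended without spl7 shoot deficient replicate 2, which also ended all the calls just named except HSP21 and PCR2. PETE2, MT2A, HSP21, F6'H1, PAP17, PORB, CHLH, CHLM and SULTR4;2 also lost theirs without spl7 shoot sufficient replicate 2, and MT2A, HSP21, PORB, CHLM and SULTR4;2 without deficient replicate 1. The highest adjusted p of these genes ranged from 0.0553 (JAZ1) to 0.383 (LHCB1.1). MT2A changed sign when only distinct start positions were counted (log2 -0.4).

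Between spl7 and WT shoots with sufficient copper, 1 gene passed in edgeR, AT4G01610, at 11.1 ± 0.67 CPM in spl7 and 427 ± 32.0 in WT (log2 -5.26 ± 0.23, adjusted p = 3.5e-08). DESeq2 called 24 genes and 482 had an unadjusted p under 0.05. FSD1 had a log2 fold of -4.23 ± 0.69 with an adjusted p of 0.0728. The edgeR count was 10 without WT shoot sufficient replicate 1 and 5 without spl7 shoot sufficient replicate 2. Of 9 jasmonate genes none passed over all genes (4 adjusted over the list alone), the lipoxygenase gene LOX3 having log2 -2.16 ± 0.35 and JAZ10 -2.83 ± 0.59, and camera called the list lower in spl7 (adjusted p = 3.21e-08; adjusted p = 0.455 with an estimated correlation). Camera called the 8 flavonoid genes higher (adjusted p = 0.0198; adjusted p = 0.575 with an estimated correlation) with 0 past the threshold (0 adjusted over the list alone), the regulator TT8 having log2 0.53 ± 0.27.

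Under copper deficiency 28 genes differed between spl7 and WT shoots, 18 higher and 10 lower in spl7. CSD1 (log2 4.44 ± 0.23, adjusted p = 1.49e-07), ARPN (4.07 ± 0.41) and CCS (3.78 ± 0.22) were higher, as were HIPP22, a heavy metal-associated protein gene (2.71 ± 0.37), the early light-induced ELIP1 (2.56 ± 0.35), HSP70-4 (2.51 ± 0.34), SUS3 (2.29 ± 0.27), DI21 (2.26 ± 0.30) and the blue copper-binding protein gene BCB (2.13 ± 0.27). FSD1 was lower by log2 -10.97 ± 0.63, AT4G28790 at least 28.7-fold, AT4G01610 by -5.33 ± 0.22 and YSL2 by -5.06 ± 0.47. The thylakoid calcium-sensing protein gene CaS (-1.83 ± 0.21) and the carbonic anhydrase gene CA1 (-1.06 ± 0.19) were lower.

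By list, 2 of 5 copper deficiency genes were lower in deficient spl7 shoots (4 adjusted over the list alone; median log2 fold -5.06, or -3.38 with bounds; adjusted p = 0.0809 with an estimated correlation). Of 6 microRNA targets 4 were higher (4 adjusted over the list alone), and their camera call held with an estimated correlation (adjusted p = 0.0178). Of 2 heat shock genes HSP70-4 passed (2 adjusted over the list alone). None of the 19 photosynthesis genes passed in edgeR (15 adjusted over the list alone), PSBQ1 having log2 -0.98 ± 0.21, and camera called them lower in spl7 (adjusted p = 4.78e-14; adjusted p = 0.267 with an estimated correlation). Camera also called the chlorophyll and sulfate lists lower (adjusted p = 0.146 and 0.261 with an estimated correlation) and the iron uptake and flavonoid lists higher (adjusted p = 0.604 and 0.636 with an estimated correlation). Each had 0 members past the threshold over all genes (5, 1, 0 and 1 adjusted over the list alone), the chlorophyll gene PORB having log2 -0.61 ± 0.22. The count of 28 became 15 without WT shoot deficient replicate 2 and 15 without spl7 shoot deficient replicate 2. The split of 18 and 10 became 14 higher and 16 lower without WT shoot deficient replicate 1, and 28 higher and 25 lower by DESeq2. Without WT shoot deficient replicate 2 the calls of HIPP22 (adjusted p = 0.0533), ELIP1 (0.076), HSP70-4 (0.0533), AT4G28790 (up to 0.312) and CA1 (up to 0.223) ended, AT4G28790 and CA1 also without either spl7 shoot deficient library and HSP70-4 without spl7 shoot deficient replicate 2. AT4G28790 and COX5B-1 (log2 1.42 ± 0.26, up to 0.211) lost theirs without WT shoot deficient replicate 1 too.

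In shoots 8 genes passed the interaction of genotype and copper, 5 with higher and 3 with lower folds in spl7. ARPN (4.51 ± 0.51), CSD1 (4.42 ± 0.29) and CCS (3.82 ± 0.29) fell in WT shoots and passed no test of the response in spl7 shoots. BCB (3.0 ± 0.38, adjusted p = 0.00516) stood at 261.5 ± 39.4 and 186.4 ± 28.2 CPM in sufficient and deficient WT shoots and at 142.2 ± 32.6 and 818 ± 327 CPM in spl7, and CaS (-1.83 ± 0.29) at 559 ± 9.72 and 1234 ± 38.3 CPM in WT against 557.5 ± 15.0 and 346.5 ± 101 CPM in spl7. FSD1 (-6.74 ± 1.45, adjusted p = 0.279) and YSL2 (-4.51 ± 0.81, adjusted p = 0.0784) did not pass, so 0 of 5 copper deficiency genes passed (2 adjusted over the list alone; adjusted p = 0.0589 with an estimated correlation). Of 6 microRNA targets 3 passed (4 adjusted over the list alone), and the camera call held with an estimated correlation (adjusted p = 0.0147). No member of the photosynthesis, chlorophyll and sulfate lists passed by edgeR, while camera called these lists (adjusted p = 0.427, 0.284 and 0.148 with an estimated correlation; 0, 0 and 0 adjusted over the list alone) and the jasmonate list (adjusted p = 0.228 with an estimated correlation; 4 adjusted over the list alone). The count was 5 without WT shoot sufficient replicate 2 and 14 without spl7 shoot deficient replicate 1. ARPN, CSD1, CCS and BCB passed whichever library was left out, whereas CaS lost its call in 6 of 8 cases (adjusted p up to 0.203), among them without WT shoot deficient replicate 2.

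Within WT, the copper response differed between roots and shoots for 25 genes, 17 with the higher fold in roots. The fit took root and shoot libraries as independent, and a pairing of tissues was not tested. FRO4 rose in roots and stood at 13.9 ± 3.61 and 11.4 ± 3.24 CPM in sufficient and deficient shoots (difference of log2 folds 5.71 ± 0.75, adjusted p = 0.00193). CCS fell less in roots than in shoots (1.80 ± 0.29). FMO1 (-4.71 ± 0.65, adjusted p = 0.00193), AT3G22600, a lipid transfer protein gene (-2.47 ± 0.34), F6'H1 (-3.0 ± 0.5) and the glutathione transferase gene GSTF7 (-2.13 ± 0.36) had higher folds in shoots. Camera called the copper deficiency list (adjusted p = 0.00332; adjusted p = 0.0856 with an estimated correlation), with 1 of 5 members past the threshold, FRO4 (2 adjusted over the list alone). Single members passed for microRNA targets (CCS, 1 of 6, and 2 adjusted over the list alone), iron uptake (F6'H1, 1 of 15, and 1 adjusted over the list alone) and salicylate (FMO1, 1 of 6, and 1 adjusted over the list alone). The split of 17 and 8 turned to 4 higher in roots and 12 lower without WT shoot deficient replicate 2 (16 calls) and to 3 and 4 without WT root deficient replicate 2 (7 calls). It was 2 and 2 without WT shoot sufficient replicate 2 (4 calls), and 7 and 6 or 8 and 6 without WT root sufficient replicate 1 or 2 (13 and 14 calls). FMO1, AT3G22600, CCS and NRT2.7 passed whichever library was left out. FRO4 had a difference of 8.83 without WT root sufficient replicate 1. NRT2.7 carries the limit of strand given above. Its 5' part held 129 and 216 CPM in deficient roots and 136 and 215 CPM in deficient shoots. Its 3' part held 0.719 and 1.58 CPM in sufficient roots and 49.7 and 26.8 CPM in sufficient shoots. The smaller NRT2.7 fold in shoots thus includes a higher level with sufficient copper. Without WT shoot sufficient replicate 2 FRO4, F6'H1 and GSTF7 did not pass (adjusted p up to 0.0513, 0.111 and 0.11).

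Calls of WT and spl7 were compared for shared genes. In roots 9 of the 19 genes that rose in WT also rose in spl7 (expected 0.6, Fisher's exact p = 2.06e-09), and 1 of 6 fell in both (expected 0.2, p = 0.174 by Fisher's exact test). In shoots 61 of 74 rose in both (expected 2.5) and 18 of 55 fell in both (expected 1). Between tissues, 5 genes rose and 4 fell in both roots and shoots of WT, and 69 rose and 33 fell in both tissues of spl7 (expected 8 and 3.6), 8 further calls having opposite directions. The expected counts and Fisher's tests treat genes as independent units, so they do not cover variation between experiments. Of all 35 camera calls the 9 that held with an estimated correlation are those of the copper microRNA targets in the WT response, the deficient genotype comparison and the interaction of both tissues, and of the copper deficiency response in the corresponding root comparisons. Median, mean and camera direction differed in sign in 33 of 198 tests of a list, of which camera called 0. In 5 of these a member passed: median and mean were 0.06 and -0.2 for the clock list and -0.02 and 0.11 for the peroxide enzymes in spl7 roots, and -0.01 and 0.08 for iron uptake and -0.06 and 0.03 for phosphate in spl7 shoots, while iron uptake between tissues (-0.18 and -0.33) had the camera direction up. Among the others, the copper deficiency list in spl7 roots had -0.43 and 0.11.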

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

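All tests of explanations in this part were chosen after the result they address had been seen, while the interaction tests were fixed beforehand. The copper response differed between spl7 and WT in roots for 65 genes by the edgeR interaction test. Genes with a higher log2 fold in spl7 were AZI1 (difference 4.31), VSP1 (4.0), CSD1 (3.81), PYD4 (3.26), TRE1 (3.06), OSM34 (3.0), Rap2.6L (2.74), AT1G15125 (2.65), CCS (2.55), ARPN (2.36) and COX5B-1 (1.65). Genes with a lower log2 fold were FRO4 (-5.79, or -8.92 without WT root sufficient replicate 1), AT4G13550 (-4.14), YSL2 (-3.46), PERK14 (-2.7), AT5G14550 (-2.5), HKT1 (-2.23), AT1G20823 (-2.02), tny (-1.95) and DELTA-TIP (-1.93). The value of AT5G14550 is that of counts without strand, so the transcript behind it is uncertain, and AT4G13550 adjoins the stretch that holds MIR857 and MIR397B, so its counts carry the same limit of strand, untested here. With a group at 3 counts or fewer, FRO5 (adjusted p = 0.0258), AT5G13370 (adjusted p = 0.0167) and SUS3 (adjusted p = 0.0174) passed as well. Without spl7 root sufficient replicate 1 the calls of AZI1, VSP1, PYD4, TRE1, AT1G15125, FRO4, AT4G13550, YSL2, PERK14, AT1G20823, tny, DELTA-TIP, AT5G13370 and SUS3 ended, with highest adjusted p from 0.078 (PYD4) to 0.74 (AT4G13550). ARPN lost its call without spl7 root deficient replicate 2 (adjusted p 0.0592), FRO5 without spl7 root sufficient replicate 2, and COX5B-1 without either of these or without WT root deficient replicate 2 (highest adjusted p 0.067).

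In shoots 8 genes differed by the same test: ARPN (4.51), CSD1 (4.42), CCS (3.82), BCB (3.0), AT1G03220 (2.86), NRT2.7 (-2.46), AT5G14550 (-2.23) and CaS (-1.83), of which NRT2.7 and AT5G14550 carry the limit of strand. Without WT shoot sufficient replicate 2 the calls of AT1G03220, NRT2.7, AT5G14550 and CaS ended (highest adjusted p 0.0907, 0.09, 0.136 and 0.203).

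Between the tissues of WT 25 genes differed in their copper response. Higher log2 folds in roots were those of FRO4 (5.71, or 8.83 without WT root sufficient replicate 1), AT3G19680 (3.87), EXO (3.86), AT4G18340 (3.56), XTH15 (3.52), AT4G13550 (2.93), NRT2.7 (2.88), AT1G02610 (2.77), MYB73 (2.43), AT4G20820 (2.37) and CCS (1.8), and lower ones those of FMO1 (-4.71), AT3G13950 (-3.48), F6'H1 (-3.0), UGT76B1 (-2.68), AT3G22600 (-2.47), GSTF7 (-2.13) and ARR7 (-2.13). EP1 passed with an adjusted p of 0.0333 and a group at 3 counts or fewer. The values of NRT2.7 and AT4G13550 carry the limit of strand. Without WT shoot sufficient replicate 2 FRO4, AT3G19680, EXO, AT4G18340, XTH15, AT4G13550, AT1G02610, MYB73, AT4G20820, EP1, AT3G13950, F6'H1, UGT76B1, GSTF7 and ARR7 lost their calls, with highest adjusted p from 0.0513 (FRO4) to 0.457 (AT4G18340).

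Signal also lay in data outside the gene counts. The stretch of 1701 bases from the annotated end of AT4G13550 across MIR857 to the end of MIR397B held 180 hits in copper-deficient WT roots and 94 in copper-deficient WT shoots, and that of 390 bases from MIR398C to NRT2.7 held 13 and 19. Such hits can come from the neighbouring gene as well as from a microRNA transcript. In sufficient WT both stretches held 0 hits, and in spl7 they held 0 apart from 1 hit in the first (sufficient shoots) and 2 hits in the second (deficient shoots). In bins of 1 kb outside the windows used, 34 bins passed in the copper response of WT roots and 561 in that of spl7 roots, and 53 and 199 in WT and spl7 shoots. These bins were not assigned to genes, since the annotation is offset there.

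Counts on AT5G14550 and NRT2.7 rose in deficient WT, although both genes overlap or adjoin microRNA genes and strand is not recorded. A rise of the full-length AT5G14550 transcript as the whole cause does not hold, since the part away from MIR398B had an upper counting limit of 0.91 in log2 fold over both tissues, but a shorter 3' transcript of the gene is not excluded. The log2 fold of the part with MIR398B was higher by 2.44 in shoots (interval 1.57 to 3.29) and by 2.75 in roots (1.83 to 3.67). For NRT2.7 in shoots the 3' part had log2 -0.4, lower than the 5' part by 3.99 (interval 3.35 to 4.63), against a rise of the whole NRT2.7 transcript, and in both cases reads of a microRNA transcript fit the values. In roots the 3' part of NRT2.7 had log2 3.53 (50 hits with deficient and 5 with sufficient copper) and the 5' part 5.08 (732 and 25). Their difference of 1.55 (interval -0.26 to 3.04) cannot tell a rise of NRT2.7 from reads of the MIR398C transcript. The 5' part thus held most hits in deficient roots, whereas in sufficient shoots it held 40 hits against 101 in the 3' part. An NRT2.7 transcript covered as in sufficient shoots is therefore argued against as the whole cause in roots, but it stays open as a part.

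AT4G01610 was low in every spl7 library at both copper levels. A sequence variant that keeps reads from aligning, as the cause of the whole fall, is argued against by the parts of 100 bases with at least 20 WT hits, all 16 of which lay at or under 9.8% of WT. Parts with fewer WT hits were left out as too thin, among them bases 401 to 500 with 0 WT and 8 spl7 hits, 1 to 100 with 0 and 2, 301 to 400 with 14 and 4, and 601 to 700 with 10 and 4, so a sequence difference between the lines in such a part stays open. Carry-over of WT RNA as the source of the remaining hits is argued against by FSD1, at most 0.0484% of WT in deficient spl7, against 3.7% (interval 2.81 to 4.8) for AT4G01610 in roots and 2.48% (1.9 to 3.17) in shoots. The spl7 mutation and a separate lesion of the line, AT4G01610 lying on chromosome 4 and SPL7 on chromosome 5, cannot be told apart because the design holds 1 mutant line.

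That more genes passed in the copper response of spl7 than of WT (585 against 25 in roots, 461 against 129 in shoots) was tested against depth, which is argued against by libraries thinned to the smallest (463 against 26 in roots, 421 against 133 in shoots), and against repeated read starts, argued against by distinct start positions (600 against 26, 495 against 136). A single deviating library is argued against in roots, where spl7 held at least 213 calls without any 1 library and WT at most 62, but stays open in shoots, where spl7 fell to 82 and WT reached 123. Only libraries of the groups compared were left out, so a deviating library of the other genotype, which shares the estimate of spread, was not tested. A response of the same genes in WT at a smaller size fits in sign, since 79% of spl7 root calls and 94.4% of spl7 shoot calls had the same sign in WT, against 58.8% and 65% of all genes. Of genes called in spl7 alone, the median log2 fold in the spl7 direction was 0.2 in WT and 1.21 in spl7 roots, and 0.55 and 1.32 in shoots, where the choice by the spl7 call inflates the spl7 sizes, so this remains a hypothesis from the same data. The interaction test passed for 65 genes in roots and 8 in shoots, against 575 and 382 genes called in spl7 and not in WT. For most of the latter a response different from WT was therefore not shown. The loss of SPL7 as the reason for the larger number or size of changes was not tested.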

How the results depend on the processing

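Over 235 called values of named genes, alternatives gave 4218 values, of which 3518 kept direction and side of the threshold, 699 no longer passed and 1 reversed: MT2A in the spl7 shoot response, 0.84 by all hits and -0.4 by distinct start positions. Without the expression filter, counts of calls were 81 (WT root response), 7 (sufficient root genotypes), 474 (deficient root genotypes), 199 (root interaction), 377 (WT shoot response), 854 (spl7 shoot response), 89 (sufficient shoot genotypes), 176 (deficient shoot genotypes), 81 (shoot interaction) and 130 (WT tissue interaction). DESeq2 called 24 genes between sufficient shoots, 53 between deficient shoots, 20 in the shoot interaction and 51 in the tissue interaction. Fitting only the 2 groups compared gave 15 (WT root response) and 507 (deficient root genotypes), and all 16 libraries in one fit gave 15, 175 (deficient root genotypes), 27 (root interaction) and 13 (sufficient shoots). Between sufficient shoots, first runs alone gave 2 calls and distinct start positions 5. Of 35 camera calls 9 held with an estimated correlation. The cause was not tested for any of these changes.

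The experiment numbers were not taken as pairs, since the labels name no shared batch and the deviations of equal numbers, all positively correlated (0.016 to 0.29), passed 0.1 in only 3 of the root and 2 of the shoot pairs of groups. A shared batch is not excluded by this. With a replicate block the counts were 48 (WT root response), 136 (root interaction) and 15 (sufficient shoots). No other count moved by more than 1.5 times, but none fell. The spl7 response had 725 calls against 585 in roots and 593 against 461 in shoots. There were 429 against 310 between deficient roots and 187 against 129 in the WT shoot response. Among camera calls, the jasmonate list in the root interaction did not pass with the block (adjusted p = 0.0517), while the copper deficiency list between sufficient roots (0.0498) and the root hair and endodermis list between deficient roots (0.0331) did. With an estimated correlation and no block, camera gave the latter 2 lists adjusted p = 0.451 and 0.247. The SPL7 transcript between sufficient shoots passed with the block (log2 -1.71, adjusted p = 0.0413), with DESeq2 (-1.72), without the expression filter (-1.71) and in one fit of all libraries (-1.69). Between deficient shoots it did not pass with only the 2 groups compared (-1.77, adjusted p = 0.0553), where fewer libraries estimate the spread.

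Leaving out 1 library gave ranges of 13 to 62 calls (WT root response), 213 to 561 (spl7 root response), 1 to 10 (sufficient root genotypes), 87 to 230 (deficient root genotypes), 29 to 88 (root interaction), 17 to 123 (WT shoot response), 82 to 389 (spl7 shoot response), 1 to 10 (sufficient shoot genotypes), 15 to 30 (deficient shoot genotypes), 5 to 14 (shoot interaction) and 4 to 33 (tissue interaction). The log2 fold of SPL7 between genotypes ranged from -2.26 to -1.63 (sufficient roots), -2.69 to -2.45 (deficient roots), -1.82 to -1.6 (sufficient shoots) and -2.04 to -1.52 (deficient shoots). Counting distinct start positions, 46.9% of root interaction calls were higher against 70.8% by all hits, and 51.3% without the expression filter. A count of reads with a single hit was not run, since the deposited reads are unique already. A fit of only the groups compared was not run for interactions. The genotype interactions already used only the groups they compare, whereas the tissue interaction of WT also drew its spread from spl7 libraries. With 2 experiments a group many small changes are missed: of simulated 2-fold changes, 33% were called in roots and 32.3% in shoots.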

Other observations

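The osmotin gene OSM34 stood at 167.9 ± 8.65 CPM in sufficient and 3268 ± 200 CPM in deficient spl7 roots (log2 4.29 ± 0.35, adjusted p = 1.88e-07 by edgeR), and rose in spl7 shoots (3.28 ± 0.28) and WT shoots (1.75 ± 0.28) as well, while WT roots had 1.29 ± 0.31 with an adjusted p of 0.117. The aminotransferase gene PYD4 rose in spl7 roots from 11.3 ± 1.82 to 238.4 ± 38.7 CPM (log2 4.33 ± 0.41) and fell in spl7 shoots from 448.3 ± 3.0 to 253.9 ± 5.87 CPM (-0.82 ± 0.22, adjusted p = 0.0455), a difference between tissues that was not tested for spl7. The threonine aldolase gene THA1 rose in spl7 roots from 20.5 ± 5.97 to 250.4 ± 28.5 CPM and in WT roots from 7.48 ± 3.14 to 30.2 ± 19.1 CPM (log2 3.52 ± 0.34 and 2.0 ± 0.39), with an interaction of 1.52 ± 0.54 that did not pass (adjusted p = 0.29).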
